A study of Daphnia magna with 22 samples.

How the data were processed

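Gene expression was measured by RNA sequencing in 22 libraries of Daphnia magna, each made from the body of 1 female of the GB or IL clone without her newly laid eggs. Per the labels' protocols, RNA was extracted with a Qiagen RNeasy kit and libraries were made with a directional kit (NEBNext Ultra II), so that reads keep their strand. The values are raw counts of sense-strand reads per gene model, per the labels and the deposited table. The submitters' processing notes name FastQC, Trim Galore 0.4.5, STAR and DESeq2; the counting tool, genome build and annotation are not given in the sources used here. Per the labels, control and CR animals were put through the same daily handling in plain medium as the exposed animals, and the clones shared the exposure solutions.

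Samples were grouped by the letters of their titles. C, B and N stand for control, BHB and NMN, and L was read as the low-food CR group by elimination, since no label spells it out. Per the deposited design text, the animals of a clone descended from 3 stock females, each of which started a cohort that was divided over the groups. The labels do not say whether the title numbers mark these cohorts, so animals of different groups can share a lineage that the fit leaves out. Each female counts as 1 replicate, with 3 per clone and group and 2 per clone for NMN. No 2 libraries of a group agreed within sampling noise (chi-square per degree of freedom of 47.9 or more in every pair).

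The table had 14657 rows with 9831 distinct IDs, of which 13368 rows had protein accessions and 1289 gene-model IDs. There were 1546 IDs on more than 1 row (6372 rows, 1038 of the tested ones); each row was kept as a gene model of its own, and a suffix tells repeats of an ID apart. In 5500 rows no library had a count. None of the IDs (0 matched) was found in the RefSeq gene table of assembly GCF_020631705.1, and the file pairs no ID with a name. The gene lists fixed before the data were examined therefore have no members here and their tests were not run, and the genes to name were limited to 2 IDs in each direction per comparison.

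Gene models were kept with edgeR's filterByExpr on the 8 groups of clone and treatment (minimum count 10, minimum total 15), which left 4965. Counts were scaled by TMM and tested with the quasi-likelihood F test of edgeR 4.0.16 (robust fit) in R 4.3.3, over all 22 libraries with terms for clone and treatment. Interactions came from a fit with 8 group means. P-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. The biological coefficient of variation was 36.1%. Standard errors were derived from the log2 fold change and its F statistic. CPM are counts divided by the TMM-scaled library size, in the usual unit of that name, and log2 CPM used a prior count of 2. The named gene models were those with the largest rise and the largest fall past the threshold with a mean log2 CPM of at least 1 and, for treatments, the same sign in both clones; where fewer than 5 gene models passed, those with the smallest p in each direction were named as not past it. Parts of the rule that need gene names named none. Ratios of reads in low-count gene models have exact conditional binomial intervals on summed counts, which cover counting error only.

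The fit was tested on simulated counts drawn from the real means and library sizes with 200 changed genes, 50 at each of 4 fold sizes, and with no variation shared by genes. It recovered 36%, 58%, 88% and 92% of changes of 1.5-fold, 2-fold, 4-fold and 8-fold in the CR comparison with 2.14% false calls, and called 1, 0 and 0 genes in unchanged simulated CR, BHB and NMN comparisons. Depth ranged from 8503141 to 14353733 counts per library and was higher in control, so the lowest-count gene models have the least precision.

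The alternatives chosen before the data were examined were DESeq2 1.42.0, median-ratio size factors, no low-count filter, a filter of 1 CPM in 6 libraries, an adjusted p of 0.1, the replicate number as a block, the compared groups alone, each clone alone, the average of within-clone contrasts and each library left out in turn. Added after seeing the data were 1 surrogate variable (sva 3.50.0), library number as a linear term, thinning to the smallest total, removal of the 50 most abundant rows, summing rows of 1 ID, leaving out 5 libraries and leaving out the 3 IL libraries numbered 1. Correlations of effects were set against 100 simulations of unchanged groups and against 18 splits of the controls. Each simulation dealt the scaled deviations of all 22 libraries from their group means again within clone. The groups of a simulation share its simulated control, which is not the real one. The overlaps with the CR calls were set against 50 simulations with BHB or NMN drawn from the control means and fitted dispersions, and signs across clones against all 20 assignments of control and CR labels in the clone not used to choose. Animals exposed to BHB and NMN together, which the labels describe, were not analysed here.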

Results

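RNA was sequenced from whole bodies of 22 adult females of the water flea Daphnia magna, a crustacean that reproduces clonally. The eggs that each female had just laid were taken out of the brood pouch before extraction. The animals belonged to 2 clones, GB from a permanent lake in London and IL from a pond in Jerusalem that dries in summer. Each clone was raised as a full-diet control (400000 algal cells per mL), under caloric restriction (CR, 100000 cells per mL), or on the full diet with daily 2 h baths of beta-hydroxybutyrate (BHB, a ketone body, 2.5 mM) or nicotinamide mononucleotide (NMN, a precursor of the coenzyme NAD+, 0.1 mM). There were 3 females per clone in the control, CR and BHB groups and 2 per clone in the NMN group. Libraries held 8503141 to 14353733 counted reads, with 13436216 ± 853264 in control (SD, n = 6), 11195612 ± 859581 in CR (n = 6), 11350367 ± 2093751 in BHB (n = 6) and 11241848 ± 1728020 in NMN (n = 4). The count table identifies gene models by protein accession or gene-model ID and pairs none of them with a gene name, so that results are given by ID and as counts of gene models.

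The question of the CR comparison was which transcripts differ between animals on the restricted diet and fully fed animals of the same clones. Of 4965 gene models tested, 167 differed, of which 102 rose and 65 fell in CR. Changes over 2-fold were found in 49 of them, 21 higher and 28 lower. The gene models with the largest falls were KZS08918, from 54.2 ± 83 CPM (library-size-scaled counts; SD, n = 6) in control to 0.275 ± 0.249 in CR (n = 6), and genemark-falcon_000004F-processed-gene-32.11, from 39.9 ± 41.8 to 1.88 ± 1.22. Their log2 fold changes were -7.03 ± 1.36 (SE, adjusted p = 0.00712) and -4.05 ± 0.635 (adjusted p = 0.0018), and both lay below every control library of the same clone in 6 of 6 CR libraries. GB control replicate 3 held 2859 of the 4313 control reads of KZS08918, and the control mean was 22.1 CPM without it (log2 fold change -6.18); that of genemark-falcon_000004F-processed-gene-32.11 was 25.95 without GB control replicate 2. The largest rises were in KZS14007, from 53.9 ± 22.8 to 349.5 ± 245 CPM (log2 fold change 2.46 ± 0.574, adjusted p = 0.0218), and KZS13733, from 133.8 ± 136 to 443.2 ± 213 CPM (2.21 ± 0.531, adjusted p = 0.0254), each above the control mean of its clone in 6 of 6 CR libraries. The control mean of KZS13733 was 84.8 CPM without GB control replicate 3.

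**Figure D1:**
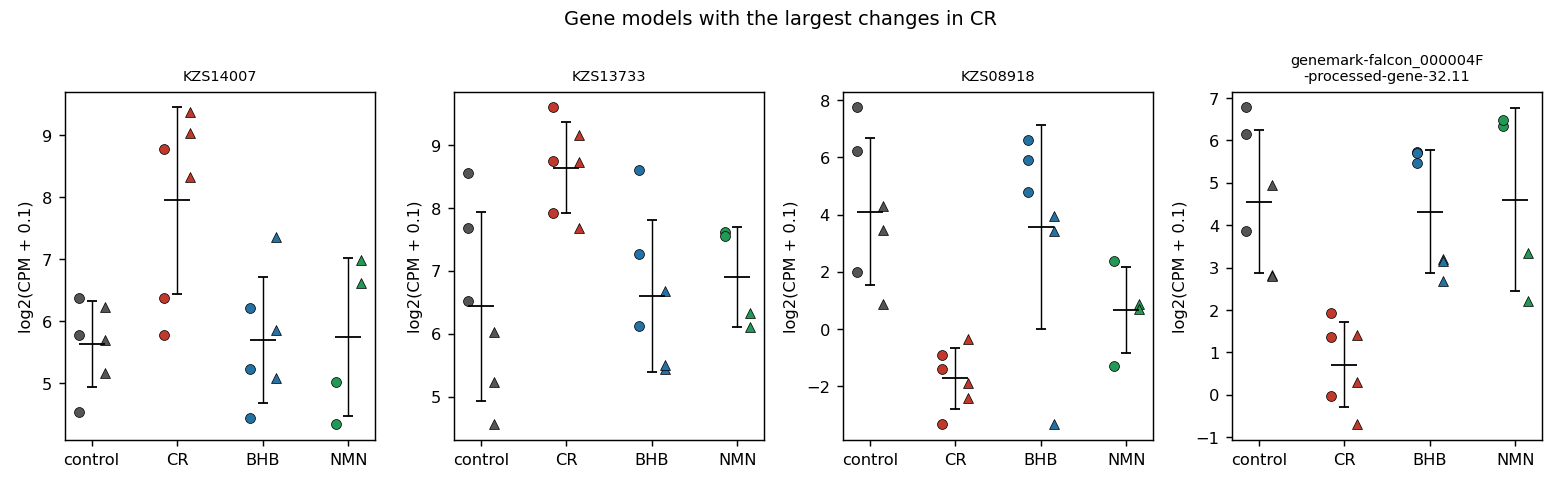
Abundance of the gene models with the largest changes in CR, as log2(CPM + 0.1) on the y axis, by treatment on the x axis; circles are GB and triangles IL libraries, bars the mean ± SD of the plotted values. In all 6 CR libraries KZS08918 and genemark-falcon_000004F-processed-gene-32.11 lie below every control library of their clone.

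The most abundant gene models shifted as well. The 10 most abundant held 16.4% of all counts; 3 of them fell and 1 rose in CR. The most abundant of all went from 52500 ± 24200 CPM in control to 11100 ± 11100 in CR (log2 fold change -2.28 ± 0.532 SE, adjusted p = 0.0213). Its CR mean was 6809 CPM without IL CR replicate 3 (log2 fold change -2.96), and its call was lost without IL control replicate 1 (adjusted p 0.054) or GB CR replicate 1 (0.0607). Together, these 10 took 17.9 ± 2.11% of counts in control, 13.2 ± 1.94% in CR, 18.8 ± 2.62% in BHB and 14.4 ± 0.982% in NMN (SD). Labels exchanged within clone gave a two-sided exact permutation p of 0.01 for CR (adjusted 0.03 over the 3 treatments), 0.465 for BHB (adjusted 0.465) and 0.03 for NMN (adjusted 0.045, n = 4), where the smallest values these designs allow are 0.005 for CR and BHB and 0.01 for NMN. Most of the shift lay in the most abundant gene model, which took 5.06 ± 2.38% in control, 1.16 ± 1.08% in CR and 2.00 ± 0.49% in NMN. Its share did not pass either (two-sided exact permutation p = 0.01 for CR, adjusted 0.06, and 0.05 for NMN, adjusted 0.15, over the same 6 tests as the next values). The other 9 together took 12.9 ± 1.57%, 12 ± 1.46% and 12.4 ± 0.582% (two-sided exact permutation p = 0.315 for CR, adjusted 0.54, and 0.55 for NMN, adjusted 0.575, over 6 tests). In CR these 9 held falls (KZS16921, log2 fold change -1.22, edgeR adjusted p = 0.00358, and KZS21034, -1.42, 0.0235) and a rise (KZS07197, 0.575, 0.0468). None of the 10 passed on its own in NMN (the most abundant had an adjusted p of 0.937).

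The sign of the CR changes was followed in each clone. In a fit with a separate mean for each of the 8 groups, the 102 gene models that rose were all higher in GB and 101 of them in IL, and the 65 that fell were lower in both clones; these were chosen by a fit that averages the clones, which favours such agreement. Of the 29 gene models that passed in GB alone, 27 (93.1%) had the same sign in IL, against up to 82.8% in the other 19 assignments of the IL labels (one-sided exact permutation p = 0.05, the smallest possible; adjusted 0.075 over 3 tests). Of the 200 with the smallest p in GB, 152 (76%) had the same sign in IL (permutation p = 0.05, adjusted 0.075), and of the 200 with the smallest p in IL, 161 (80.5%) had it in GB (permutation p = 0.15, adjusted 0.15). In the 8-group fit, whose spread comes from all libraries, 51 gene models passed within GB and 61 within IL, of which 39 and 40 were among the 167. A fit of the IL libraries alone called 0 (682 at an unadjusted p under 0.05 in edgeR), where that of GB alone called 29, at 3 animals against 3. All 6 CR libraries carry library numbers 17 to 22 and no other library does. With library number as a linear term 1 gene model was called, DESeq2 called 343, 1 surrogate variable gave 362, a fit of the control and CR libraries alone gave 88, an adjusted p of 0.1 gave 306 and leaving out GB CR replicate 1 gave 111. The calls of KZS14007 and KZS13733 were lost without GB control replicate 1 (adjusted p 0.0518 and 0.0581), IL control replicate 1 (0.054 and 0.063), IL control replicate 2 (0.0559 and 0.0612), IL control replicate 3 (0.0511 and 0.0553) or GB CR replicate 3 (0.0927 and 0.0584), and that of KZS13733 also without IL CR replicate 2 (0.0551).

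BHB was compared with control to ask whether a ketone body given to fully fed animals changes the transcriptome. No gene model passed the threshold in edgeR (0 of 4965; 151 at an unadjusted p under 0.05; 0 in DESeq2), and the smallest adjusted p was 0.999. In BHB, KZS06330 measured 14 ± 2.78 CPM against 9.7 ± 2.71 in control (log2 difference 0.54 ± 0.144 SE, adjusted p = 0.999) and was above its clone's control mean in 6 of 6 libraries. The gene model maker-falcon_000021F-snap-gene-15.67 measured 1.72 ± 0.467 against 2.94 ± 0.71 CPM (-0.77 ± 0.205, adjusted p = 0.999) and was below that mean in 6 of 6. KZS15145 had 19 reads in all BHB libraries against 2 in all control libraries, a ratio of 11.3 with a 95% counting interval of 2.72 to 99.7, and 9 against 2 without GB BHB replicate 3. Of the 19 reads 18 were in GB, both control reads were in GB control replicate 1, without which control is at 0, and the CR libraries also had 19. KZS03586 had 15 against 1290, of which 1108 were in GB control replicate 2, so that 182 remained without it. All 1290 were in GB, and IL had 0 reads in control and 1 in BHB, so this fall was seen in GB only. KZS15145 and KZS03586 both had an adjusted p of 0.999. On simulated counts the same fit recovered 62% of changes of 2-fold and 96% of changes of 8-fold in the BHB comparison. These counts hold no variation shared by gene models, and such simulations called more gene models than the data in the comparisons with CR, so recovery in the data can be lower.

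NMN was compared with control in the same way. No gene model passed in edgeR (0 of 4965; 256 at an unadjusted p under 0.05), the smallest adjusted p was 0.17, and DESeq2 called 4. The smallest p belonged to KZS20190_1, at 53.6 ± 10.9 CPM in NMN (SD, n = 4) against 29.9 ± 4.07 in control (log2 difference 0.83 ± 0.156 SE, adjusted p = 0.17) and above every control library of its clone in 4 of 4 NMN libraries. DESeq2 gave this gene model an adjusted p of 0.00383, and its ID is on 2 rows of the table, between which reads could be divided. KZS13212 measured 208.9 ± 53.2 against 331.6 ± 80.5 CPM (-0.67 ± 0.186, adjusted p = 0.818). KZS15145 had 24 reads in NMN against 2 in control, a ratio of 20.1 (95% counting interval 4.98 to 175), and 7 without GB NMN replicate 1. All 24 were in GB, and control is at 0 without GB control replicate 1. KZR98830, whose ID is also on 2 rows, had 3 against 111, or 22.1 times fewer at equal depth (7.38 to 109). The 3 were all in GB NMN replicate 1, and 50 of the 111 remained without GB control replicate 3. Of the 111, 110 were in GB, so this fall rests on the GB animals. KZS15145 and KZR98830 both had an adjusted p of 0.818. On simulated counts the fit recovered 54% of 2-fold and 88% of 8-fold changes in the NMN comparison, with the same limit as for BHB.

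The series sets BHB and NMN beside CR, and the direct comparisons ask how far each treatment lay from it. The CR libraries alone carry library numbers 17 to 22, so a preparation or sequencing step shared by them would enter both comparisons. Between BHB and CR 150 gene models differed, 66 higher and 84 lower in BHB. All 102 gene models that rose in CR measured lower in BHB than in CR, and 59 of them passed the threshold; all 65 that fell measured higher, and 38 passed. The lists share the CR libraries, so these 97 calls were set against BHB libraries simulated as unchanged from control, which gave 146 ± 10 shared of 300 calls on average (SD, 50 simulations, 126 to 167); independent lists would share 2.59. The simulated libraries hold no variation shared by gene models, so the gap between 146 and 97 was not read as a difference. KZS14007 was lower in BHB than in CR (log2 difference -2.36 ± 0.566 SE, adjusted p = 0.0293), and genemark-falcon_000004F-processed-gene-32.11 was higher (3.43 ± 0.628, adjusted p = 0.00741). The count was 323 with DESeq2, 316 with 1 surrogate variable and 0 with library number as a linear term (375 at an unadjusted p under 0.05 in edgeR), and fell to 87, 85, 90 and 91 without GB BHB replicate 1, GB BHB replicate 3, GB CR replicate 3 and IL CR replicate 2.

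Between NMN and CR 22 gene models differed, 11 in each direction, and 20 of them were among the 167, against 0.37 for independent lists. NMN libraries simulated as unchanged from control gave longer lists, of 165 gene models on average, of which 92.9 ± 6.39 were shared (SD, 50 simulations), and this gap was not read as a difference either. Of the named CR gene models, genemark-falcon_000004F-processed-gene-32.11 differed (log2 difference 3.90 ± 0.672 SE, adjusted p = 0.0122), while KZS14007 (-2.43 ± 0.664, adjusted p = 0.122) and KZS08918 (3.03 ± 1.45, adjusted p = 0.51) did not pass. KZS08918 was also low in NMN, at 2.16 ± 2.05 CPM (SD, n = 4) and 99 reads against 4313 in control, without passing against control. In BHB it measured 35 ± 36.4 CPM (n = 6). The count was 105 with DESeq2, 65 with 1 surrogate variable, 14 with no low-count filter and 1 with library number as a term. Without a library it was 7 (GB NMN replicate 1), 1 (GB NMN replicate 3), 12 (IL NMN replicate 2), 14 (IL NMN replicate 3) or 14 (GB CR replicate 3).

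Between BHB and NMN, 1 gene model differed: KZS20190_1, named here after its values were seen, was lower in BHB (27 ± 5.51 CPM, n = 6) than in NMN (53.6 ± 10.9, n = 4), with a log2 difference of -0.99 ± 0.156 (SE, adjusted p = 0.0172). The call was lost without GB BHB replicate 1 (adjusted p 0.0728), GB NMN replicate 3 (0.154), IL NMN replicate 2 (0.133) or IL NMN replicate 3 (0.145), and also in the compared groups alone (0.0833), with library number as a term (0.321) and without the 5 libraries highest on the largest axis of within-group variation (0.0864). The compared groups alone called 2 other gene models. DESeq2 called 7 gene models, and the count was 4 without IL BHB replicate 3 and 2 without IL BHB replicate 2, GB control replicate 2, IL control replicate 3 or IL CR replicate 1.

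**Figure D2:**
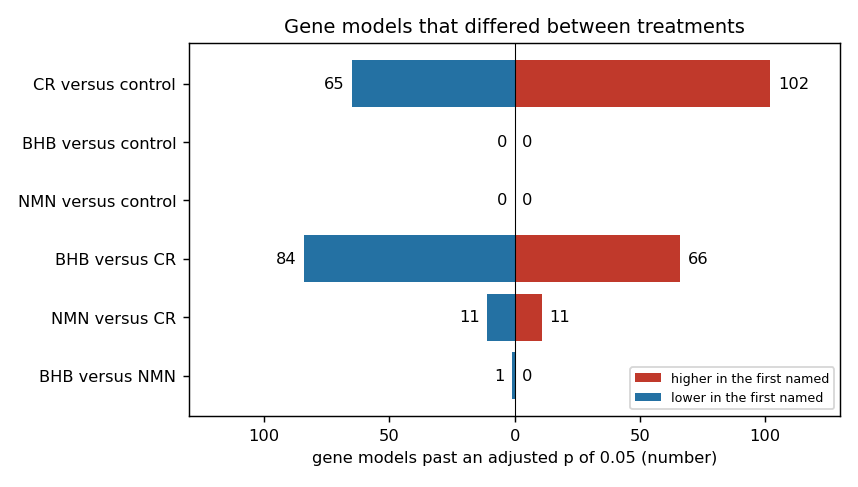
Number of gene models past an adjusted p of 0.05 in each comparison of treatments; bars to the right count those higher, and bars to the left those lower, in the treatment named before "versus". CR differed from control in 167 gene models, and BHB and NMN in 0.

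The 167 CR gene models were followed in the other treatments. Of the 102 that rose in CR, with a median log2 fold change of 0.74, 81 were above control in BHB (median 0.11) and 92 in NMN (median 0.18). Of the 65 that fell, with a median of -0.85, 46 were below control in BHB (median -0.07) and 59 in NMN (median -0.22). A score per library, the mean over the 167 gene models of the log2 difference from the control mean with the sign of the CR change, was 0.926 ± 0.129 in CR (SD, n = 6), 0.121 ± 0.134 in BHB (n = 6) and 0.286 ± 0.0447 in NMN (n = 4), with a spread of 0.0673 among the 6 control libraries. The 167 were chosen with these control libraries, which raises every treatment's score. The BHB and NMN libraries entered the filter, the clone term and the dispersions of that fit. All 4 NMN libraries scored above every BHB library of their clone, a difference of 0.165 (two-sided exact permutation test within clone, p = 0.04, smallest possible 0.01, chosen after seeing the data). With the 88 gene models called in the control and CR libraries alone, the difference was 0.0985 (two-sided exact permutation p = 0.14), and 2 of 4 NMN libraries lay above every BHB library of their clone. The mean library number was 13.2 in NMN and 6.33 in BHB, and the slope of the score on library number within groups gives 0.032 ± 0.047 (SE) for that gap. When 200 gene models were chosen with part of the control and CR libraries and measured in the others, the median over 90 draws was 0.52 in CR, -0.0237 in BHB and 0.0871 in NMN; it was above 0 in 86, 38 and 72 draws, which overlap in libraries and are not independent.

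**Figure D3:**
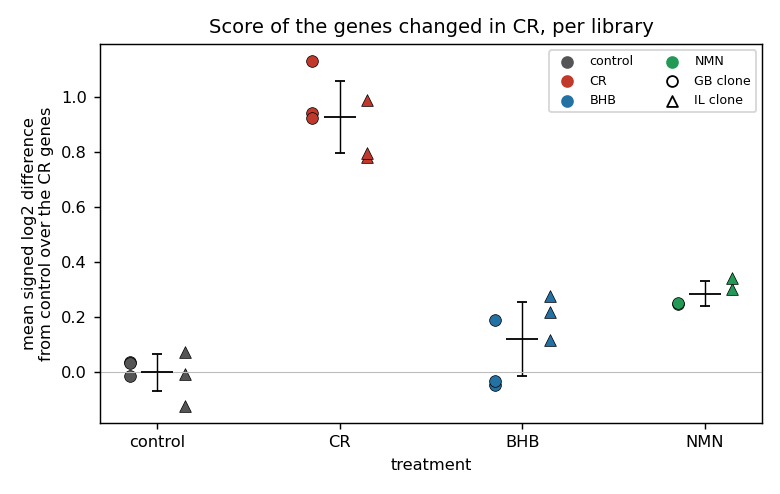
Score of the 167 CR gene models in each library (y axis, mean signed log2 difference from the control mean) by treatment (x axis); circles are GB and triangles IL libraries, bars the mean ± SD. The CR libraries lie between 0.78 and 1.13, the NMN libraries between 0.246 and 0.341 and the BHB libraries between -0.0482 and 0.276.

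Across all 4965 gene models, which are not independent replicates, the log2 fold changes of CR and BHB against the same controls had a Pearson r of 0.347 (Spearman rho 0.318), those of CR and NMN 0.447 (0.419) and those of BHB and NMN 0.259 (0.247). Simulated unchanged groups that share a simulated control gave 0.486 ± 0.209, 0.4 ± 0.233 and 0.453 ± 0.212 (SD over 100 simulations), and 80, 45 and 89 of the 100 reached the observed r. These simulations dealt the libraries' deviations from their group means again within clone, so the real controls were not kept. The covariances were 0.0482, 0.069 and 0.0259 against simulated values of 0.0601, 0.0544 and 0.0625, differences of -0.0119, 0.0146 and -0.0367. With different control libraries in each comparison the median r over 18 splits was -0.0617 (-0.423 to 0.125) for CR and BHB, 0.03 (-0.4 to 0.263) for CR and NMN and -0.166 (-0.636 to 0.0328) for BHB and NMN.

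The clones differed far more than the treatments. Between GB and IL 2199 gene models differed, 1114 higher and 1085 lower in GB, and 671 of them by over 4-fold (386 higher and 285 lower in GB). KZS21465 measured 179.9 ± 9.47 CPM in GB (SD, n = 11) and 1.1 ± 1.3 in IL (n = 11), and KZS20154 measured 69.6 ± 12.1 and 0.49 ± 0.719 (log2 differences 7.39 ± 0.451 and 7.22 ± 0.475 SE, adjusted p = 8.64e-11 and 1.96e-10). The 3 IL libraries numbered 1 were higher than other IL libraries in both, and without them the log2 differences were 8.70 and 8.43; that of KZS20154 was 7.90 without IL CR replicate 1 alone. In the other direction KZS01535 measured 0.219 ± 0.218 in GB and 72.7 ± 6.06 in IL, and KZS14395 0.0634 ± 0.0818 and 22.1 ± 2.61 (log2 differences -8.35 ± 0.374 and -8.28 ± 0.351, adjusted p = 3.59e-13 and 6.16e-14). Of the 167 CR gene models, 72 (43.1%) also differed between the clones, against 44.3% of all tested. Among the 671, 25.8% shared their ID with another tested row, against 12.8% of all tested rows, and reads of such copies could be divided between rows. In the 6 control libraries alone 772 differed.

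**Figure D4:**
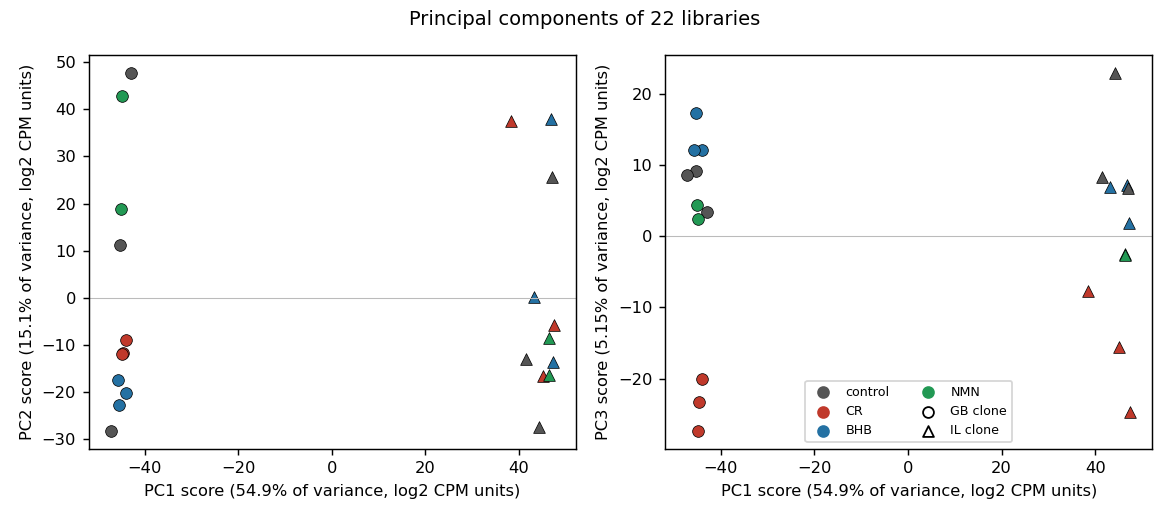
Scores of the 22 libraries on principal components 1 and 2 (left) and 1 and 3 (right) of log2 CPM, with the percentage of variance on each axis; colours are treatments, circles GB and triangles IL. Component 1 holds 54.9% of the variance with GB between -47.2 and -43 and IL between 38.4 and 47.5, and on component 3 (5.15%) the CR libraries lie between -27.4 and -7.73 and the control libraries between 3.41 and 23.1.

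Principal component 3 set the CR libraries apart, at -19.8 ± 7.19 (SD, n = 6). They are also the only libraries numbered 17 to 22. NMN scored 0.443 ± 3.52 (n = 4), and BHB (9.6 ± 5.4, n = 6, range 1.84 to 17.4) and control (9.91 ± 6.78, n = 6, 3.41 to 23.1) overlapped. Component 2 (15.1% of the variance) varied among animals of the same group, from -28.2 to 47.8 within control alone.

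Whether the clones responded differently was tested as the interaction of clone and treatment in the fit with 8 group means. No gene model passed for CR, BHB or NMN in edgeR (0 each), and 411, 377 and 154 had an unadjusted p under 0.05. For CR the smallest edgeR adjusted p was 0.1. DESeq2 called 26 for CR (2 with a positive and 24 with a negative interaction), 1 for BHB and 0 for NMN. It gave no adjusted p for 1554 of the 4965 gene models in the CR interaction, so its 26 come from a smaller set. For CR, 1 surrogate variable gave 10, no low-count filter 3, and leaving out 1 library gave 3 (GB BHB replicate 2), 3 (GB BHB replicate 3), 4 (GB control replicate 1), 1 (GB CR replicate 3) or 4 (IL CR replicate 1). For BHB it gave 1 without GB control replicate 1, and for NMN 1 without GB NMN replicate 1 or IL NMN replicate 2. KZS14007 measured 3.60 times control in CR in GB and 9.34 times in IL (edgeR adjusted p = 0.316 and 0.0737), and KZS13733 2.15 and 9.54 times (0.523 and 0.0429), and the differences between clones did not pass. In GB the value of KZS14007 rested on replicate 3 (441.3 CPM, against 83.0 and 54.7 in the other CR animals), without which the mean was 1.28 times that of control; the GB control mean of KZS13733 was 148.7 CPM with replicate 3 left out and 225.4 with it.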

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

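The comparisons of the IL libraries numbered 1 and of the split with the axis and the tests of the library numbers 17 to 22, of depth and library number on the within-group axis and of a reference closer to one clone were chosen only after the results were seen. Of 84 sets of 4 to 6 libraries checked for 1 library far from the others, 8 had one. The cut-off is meant to flag about 1 in 20 independent sets by chance. These sets share libraries, and the rate was not measured here.

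In NMN, IL replicate 2 had 8672000 counts (rounded) against 11790000 to 12330000 in the other NMN libraries. In CR, GB replicate 1 had counts in 6075 rows against 5874 to 5947 in the others. With clone and treatment removed, KZS08918 stood at -5.41 log2 CPM in IL BHB replicate 3 (0.268 to 2.06 in the other BHB libraries). In GB NMN replicate 1 it stood at -2.67 (0.792 to 1.02 in the other NMN libraries), KZS20190_1 at -0.323 (0.0813 to 0.156) and KZS13212 at -0.457 (0.141 to 0.164). KZS21465 and KZS20154 stood at 1.89 and 2.21 in IL CR replicate 1 (-0.469 to -0.332 and -0.782 to 0.0479 in the other CR libraries), at levels of a few CPM. The IL control and BHB libraries numbered 1 were also the highest of their groups: over the 3 such libraries KZS21465 measured 1.60 to 3.84 CPM and KZS20154 0.563 to 2.56, against 0.218 to 0.693 and 0 to 0.439 in the other 8 IL libraries. Over 32 gene models with a mean over 10 CPM in GB and at least 50 times less in the median IL library, the median level was 1.49 to 3.63% of the GB mean in these 3 and 0.413 to 0.957% in the other 8, and for 22 such gene models of IL it was 0.12 to 0.869% in the 11 GB libraries. The 3 were also lowest of the IL libraries on principal component 1 (38.4 to 43.1 against 44.3 to 47.5).

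Among 45 interactions of named gene models with clone, 5 stood out. KZS03586 in GB measured 34.5 ± 48.3 CPM in control, with 89.9 in replicate 2 alone, and 1.19 ± 0.482 in CR (SD, n = 3), while IL had 0 reads in its control and 12 in its CR libraries; the fitted interaction of -9.91 on the log2 scale (edgeR adjusted p = 0.0338 over the named gene models, 0.312 over all tested) is no bound, since 1 group was at 0. KZS13212 in BHB was above the GB control mean in every GB library and below the IL one in every IL library (interaction 0.77, edgeR adjusted p = 0.233). Its IL BHB libraries (256.7 to 282.1 CPM) lay within the IL control range (250.2 to 351.4 CPM). In NMN, with 2 animals per clone, genemark-falcon_000004F-processed-gene-32.11 lay in those directions (1.42), and KZS14007 (-2.09) and KZS01535 (-2.18) lay below the GB and above the IL control mean, with an edgeR adjusted p of 0.639 each. For genemark-falcon_000004F-processed-gene-32.11 the IL control mean was 14.9 CPM, and 6.93 without IL control replicate 3, against 7.29 in IL NMN. KZS01535 had 1 read in GB NMN against 8 in GB control, so its value lies near the floor.

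The CR gene models were the main pattern weighed. A steady drift with library number, measured within groups over the 16 libraries outside CR, predicts 5.7% of the mean CR change (95% interval -13.2 to 24.6%), so it would leave most of the change; with library number as a linear term the call ended at 1 gene model, since the median log2 change went from 0.77 to 0.60 in size while its standard error rose from 0.148 to 0.269, with 166 of 167 of the same sign. Without the 50 most abundant rows, 98.8% of the CR gene models that could be tested kept call and direction, and thinning every library to the smallest total gave 162 calls, 141 of them among the 167, which argues against the share of abundant transcripts and against the deeper control libraries as the whole cause. A step in preparation or sequencing shared by libraries 17 to 22 cannot be told apart from CR, since 0 libraries of another treatment carry these numbers. An effect of the diet stays open beside it.

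The CR count can be set apart from chance: 1 of 100 splits of the libraries, the real one, called as many as 167, and the highest of the others called 7. The same holds for BHB against CR (1 of 100, 150 against 8), NMN against CR (1 of 100, 22 against 1) and GB against IL (1 of 100, 2199 against 0). For BHB against NMN 5 of 100 splits called as many as 1, with a highest of 2, so chance is not excluded. With 0 calls, BHB and NMN against control and the CR and BHB interactions were reached by 100 of 100 splits; the highest other splits called 25, 2, 19 and 367, and the last value points to a structure among the samples. In that split the clone by treatment contrast of the scores on the axis weighed next was 63.8. The split with the largest contrast of 99, also 63.8, called 0. These scores have the real group means taken out, so they do not place the libraries under other labels. They cannot tell whether the axis gave the 367 calls. On principal component 2 its GB libraries labelled BHB lay at -28.2 to -20.1 and those labelled control at -17.3 to 47.8. In IL these were 0.209 to 37.9 and -27.4 to -12.9.

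The within-group axis is the largest direction of variation after removing the 8 group means, with 36.2% of that variance. Depth and library order are argued against as the whole cause. For depth the within-group correlation was 0.0382 (95% interval -0.484 to 0.54, permutation p = 0.882, adjusted 0.882). Its rho was -0.128 (permutation p = 0.55), and r was -0.108 without the 2 farthest libraries. For library order the correlation was -0.147 (-0.613 to 0.395, permutation p = 0.679, adjusted 0.882). Its rho was -0.25 (permutation p = 0.424), and r was -0.262 without the 2 farthest libraries. These intervals leave room for either as a part of the axis. Found in GB alone and in IL alone, the axis loaded on the same gene models (correlation 0.738 across gene models). A physiological state that varies among animals of both clones would give this, but no such state was identified. Random directions in GB reached up to 0.699 (median 0.349), so the margin is small. They are mixes of the same GB residuals, which hold the axis, so they set no level without it. RNA quality, which was not measured here, stays open. For treatments, the libraries were scored on the axis with the group means kept in. Differences from control were -4.35 for CR, -7.25 for BHB and 5.54 for NMN (two-sided exact permutation p = 0.785, 0.66 and 0.74). Of the 167 CR gene models, 8 (4.79%) had 50% or more of their within-group variance on it, against 10.4% of all tested. A large within-group variance makes a call less likely, so this share does not set CR apart from the axis.

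The clone differences over 4-fold were weighed last. A reference closer to one clone would lower the other clone's counts, yet the larger side held 57.5% of the 671 (exact binomial 95% interval 53.7 to 61.3%), which leaves 285 in the other direction. The interval lies above an even share, with the excess higher in GB, so a reference closer to GB stays open for a part of the 671. This interval and the next count gene models as independent, which they are not, so both can be too narrow. Reads divided between rows that share an ID stay open in part: 27.7% (21.2 to 35.1%) of the 173 such gene models with a tested copy had a copy changed in the opposite direction, while 113 had one changed in the same direction. A genetic difference between the clones also stays open.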

How the results depend on the processing

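The surrogate variable, library number, thinning, abundant rows, summed IDs, the 5 libraries left out (those highest on the within-group axis) and the 3 IL libraries numbered 1 left out were alternatives chosen after seeing the data. BHB against control stayed at 0 calls in edgeR and DESeq2 under every alternative run, and NMN at 0 except for 4 with DESeq2. For CR against control the count was 166 with median-ratio size factors, 119 with no filter, 179 with the stricter filter, 163 with IDs summed, 162 thinned, 160 without abundant rows 235 without the 5 libraries and 128 without the 3. It moved to 306 at an adjusted p of 0.1, 88 in the compared groups alone, 29 in GB alone, 0 in IL alone, 343 with DESeq2, 362 with 1 surrogate variable and 1 with library number as a covariate. The main 167 were all among the DESeq2 calls. For BHB against CR these gave 313 (adjusted p of 0.1), 323 (DESeq2), 316 (surrogate variable) and 0 (library number); for NMN against CR 64, 105, 65 and 1, with 14 with no filter and 13 without the 3 libraries. For BHB against NMN they gave 3 (adjusted p of 0.1), 2 (compared groups alone, neither of them the main call), 7 (DESeq2), 0 (library number) and 0 (5 libraries left out). GB against IL stayed within 1902 to 2559, except for 772 in control libraries alone, which are fewer samples. The CR interaction gave 3 with no filter, 1 with the replicate block, 26 with DESeq2, 10 with the surrogate variable and 1 without the 5 libraries; the BHB interaction 1 with DESeq2 and 1 without the 5 libraries; the NMN interaction 1 without the 5 libraries. With different controls in each comparison the correlation of effects became -0.0617 for CR and BHB, 0.03 for CR and NMN and -0.166 for BHB and NMN; among gene models with a mean log2 CPM of at least 3 the last was 0.0454. Apart from the library term, where the CR numbers leave little independent variation, and the smaller sample sets, the cause was not tested.

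Leaving out each library in turn gave 111 to 218 for CR against control, 0 for BHB and for NMN against control, 85 to 183 for BHB against CR, 1 to 27 for NMN against CR, 0 to 4 for BHB against NMN, 2109 to 2269 for the clones, 0 to 4, 0 to 1 and 0 to 1 for the CR, BHB and NMN interactions, and correlations of 0.279 to 0.452, 0.296 to 0.528 and 0.105 to 0.448; a lone animal in an NMN group was assumed to vary like the others. No named gene model changed direction under the 34 to 38 alternatives run for it; KZS03586 in BHB could not be tested in IL alone, where it had 1 read against 0 in control. KZS14007, KZS13733, KZS08918 and genemark-falcon_000004F-processed-gene-32.11 lost their call under 11, 13, 3 and 2 of 38 alternatives, and the 4 clone gene models under 0 of 35. The replicate number as a block gave 144 for CR, 131 for BHB against CR and 2198 for the clones. Same-numbered libraries of a clone correlated at 0.005 on average (-0.485 to 0.537, 8 of 30 pairs over 0.1), and 9 of 22 libraries correlated best with one of their own number, so the numbers were not taken as pairs. The 3 IL libraries numbered 1 did share raised levels of gene models high in GB, so a link by number stays open there. The design has 3 cohorts per clone, and the labels do not tie the numbers to them. The gene list tests and their alternatives were not run, since no ID has a name here. Depth limits gene models of a few reads most.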

Other observations

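Few gene models met a strict rule of presence in 1 clone and absence in the other. With at least 10 reads in every library of one clone and 0 in every library of the other, 1 was found in GB and 3 in IL. A single read in the other clone fails this rule, so it does not count all gene models nearly limited to 1 clone. Over 10 CPM, 32 gene models of GB and 22 of IL were at least 50 times lower in the median library of the other clone. Set against a floor of 3 counts over the clone, the gene models that met the strict rule were at least 72.7-fold to 237.9-fold higher where present. All IDs that met the strict rule are on more than 1 row of the table.

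The within-group axis involved 515 gene models with 50% or more of their within-group variance on it, 302 rising and 213 falling with the score. The highest scores were in GB control replicate 2 (37.8), IL CR replicate 1 (34.1), IL control replicate 3 (32.1) and IL BHB replicate 3 (30.4), and the lowest in GB control replicate 3 (-39.1). These scores are centred in each group, so they place a library against its own group only. GB NMN replicate 1 scored 12.8 on the axis but 0.381 on the surrogate variable, beside 0.406 in GB control replicate 2. The surrogate variable, which is built from the same residual variation, correlated with it at 0.999 in size within groups.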
